A study of Mus musculus with 11 samples.

How the data were processed

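The series compared liver RNA of db/db mice given PBS (5 samples) or an antibody against the glucagon receptor (6 samples) on two-colour Agilent mouse gene expression arrays. Per the labels, total RNA was isolated on silica columns with DNase digestion and labelled as cRNA by linear amplification, with the liver sample in Cy5 and a pooled mouse reference RNA in Cy3 on all arrays, with no dye swap. The arrays were extracted with Agilent Feature Extraction, version 11 per the submitters' processing notes and version 11.5.1.1 per the file headers. Per the file headers, the deposited scanner files give for each spot the median pixel intensity of both dyes and of the local background, as unlogged and uncorrected intensity values. They also hold processed signals, which the scanner software had background-subtracted and dye-normalized, and their log10 ratio of Cy5 over Cy3, per the file headers. Quality marks of each spot (well above background, uneven, saturated) are flags of 0 or 1 per the file headers. The authors also deposited a table of processed log2 ratios per probe, whose processing is not given in the sources used here. Set against the scanner files, these log2 values ran as Cy5 over Cy3, with no centring per gene. They differed from the values computed here by a median of 0.00329 (largest difference 0.457, lowest correlation over 39429 probes 0.999964). Their column medians were -0.0026, 0.0022, 0.00079, 0.0081 and 0.00021 for PBS replicates 1, 3, 4, 5 and 6, and -0.00096, 0.0075, 0.0015, -0.0028, 0.0054 and 0.0013 for anti-GCGR replicates 1 to 6. They correlated with the scanner's own ratio at 0.875 to 0.887. They served as an alternative. The mouse build mm9 in the file headers is that of the array design, and no coordinates were used.

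Groups and replicate numbers came from the sample titles. The design had assumed mean spot signals, and median signals were used since the columns of the files are medians. Arrays were read with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50) over all spots, and each array was normalized by loess with control spots at weight 0 and no further scaling between arrays. Spots that the scanner software marked as uneven in either dye were left out, no spot was saturated, and spots of one probe were averaged. Each array held 43020 gene spots of 39429 probes. Probes were named through the RefSeq accession they were designed on, without its version, in a table of assembly GRCm38.p6, in place of the gene name column that the design had assumed. This gave 26581 probes of 20144 genes, and 12848 probes matched no gene there and were tested only in an alternative. A probe was kept when it was well above background in Cy5 on at least 5 of the 11 arrays, and the kept probe with the highest mean brightness stood for its gene, which left 15949 genes. Among them 3988 genes had more than 1 kept probe.

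The groups were compared with lmFit and eBayes on the log2 ratios, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and a count at a log2 fold change of at least 1. Errors of log2 fold changes are the moderated standard errors of that fit. Changes of 35 gene lists (24 pathways and functions and 11 cell types) were tested with camera at a preset correlation of 0.01, adjusted over all lists, and again with an estimated correlation and with fry. A list needed at least 3 measured members. With an estimated correlation none of the 15 calls held. Fry, which asks whether the genes of a list move on balance one way, called 11 lists, 10 of them among these 15, and beside them the circadian clock list (fry adjusted p = 0.0428). The camera calls that fry did not make were amino acid catabolism (fry adjusted p = 0.0610), the urea cycle (0.108), fatty acid oxidation and ketogenesis (0.105), immediate early genes (0.0610) and oxidative phosphorylation (0.302). Adjusted p-values named camera or limma come from these fits. The value of Gcgr was also tested by exact permutation over all 462 splits of the 11 arrays.

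The genes named in the text follow a rule. It took Gcgr and 12 further genes of glucagon action chosen beforehand (Pck1, G6pc, Ppargc1a, Tat, Gls2, Cps1, Slc38a4, Cyp7a1, Fgf21, Pygl, Fasn and Cpt1a). It added the 8 largest rises and 8 largest falls among changed genes whose groups do not overlap and whose probe was well above background on every array of at least 1 group. For each list it took the 2 largest rises and the 2 largest falls past the threshold, or else the member with the smallest p. This gave 96 genes, each well above background on some array of both groups, and a few further genes that the rule picks are not reported here. Of the 96 genes, 23 had other kept probes, which differed in sign for 2 genes, Slc10a1 and Cd4. The gene Hbb-b2 and the further genes of the closing section were named after their values were seen. The groups, tests, lists, naming rule and most alternatives were set before the data were examined.

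Alternatives covered the background correction, the normalization, the reference channel, the authors' values, the filter on dim probes, the choice of probe, the variance model, array weights, the slide, the replicate number, each array left out, the list test and the threshold. The fit was tested on simulated data with 200 changed genes among the 15949 genes of this comparison. It recovered 84% of changes of 0.5 on the log2 scale and 100% of those of 1, 2 or 3, with 14 calls among unchanged genes. The simulated noise was normal and independent between genes, with no outlying array and no slide effect, so recovery on the real arrays can be lower.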

Results

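Liver gene expression was measured in db/db mice, an obese and diabetic strain that lacks a working leptin receptor. The mice were given phosphate-buffered saline (PBS) or 5 mg/kg of 3c7.v44, a monoclonal antibody against the glucagon receptor (GCGR). Glucagon, the pancreatic hormone of fasting, acts on the liver through this receptor, and the comparison asks what blocking it does to liver transcripts. There were 5 PBS samples, numbered 1, 3, 4, 5 and 6, and 6 antibody samples, numbered 1 to 6, each on its own array. Liver cRNA carried the dye Cy5 and a commercial mouse reference RNA carried Cy3 on every array, so that each value is log2 of liver over reference. The median Cy5 signal per array lay between 85 and 110 against a local background of 26 to 27 in the same unlogged scanner units, and between 66.2% and 77.1% of gene spots were well above background in Cy5. The number of arrays limits the precision. The labels do not say that each sample came from a separate mouse, so p-values measure the spread between these samples.

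The genes that differed between livers of antibody-treated and PBS mice included genes of fat synthesis, glycolysis, amino acid breakdown, cell division and connective tissue. Of 35 gene lists, 15 were called with a preset correlation between genes and 0 with an estimated correlation. As many lists were called in 17 of 100 splits of the arrays, the real one included. Among 15949 genes tested, 1432 rose and 905 fell with the antibody at an adjusted p under 0.05 (limma, 6 against 5 arrays, two-sided, Benjamini-Hochberg). At least 2-fold changes were seen in 98 genes, of which 63 rose and 35 fell. The largest rise was that of Pnpla3, a lipase-like lipid droplet protein, at 8.25-fold on its brightest probe (log2 fold change 3.04, and 0.53 on its other kept probe), and the largest fall was that of the metallothionein Mt2 at 16.4-fold (log2 fold change -4.03, and -4.74 without anti-GCGR replicate 5). The values of the groups did not overlap at all in 1061 of the 15949 genes tested, or 6.65%, where chance gives 0.433%, and 943 of these were among the changed genes. The share of rising genes depended on the scaling. It was 61.3% here, 21.2% with median centring in place of loess (578 up, 2149 down), 45.2% with the scanner software's ratio (980 up, 1187 down) and 51.4% with the Cy5 channel alone (1178 up, 1115 down).

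Genes of fatty acid and triglyceride synthesis rose together. Of 22 measured members of the list of lipogenesis and triglyceride synthesis, 14 rose, none fell and 8 did not pass, and 17 rose when adjusted over the list alone. The list's mean log2 fold change was 0.99 (camera adjusted p = 1.07e-08), with adjusted p = 0.423 with an estimated correlation. Fasn, the fatty acid synthase, went from 2.75 ± 0.86 (SD, n = 5) to 4.40 ± 0.46 (SD, n = 6), a log2 fold change of 1.65 ± 0.34 (SE, limma adjusted p = 0.0107). Pnpla3 rose by 3.04 ± 0.65 on the log2 scale (limma adjusted p = 0.0121). On PBS replicate 5 it was at 3.24, above anti-GCGR replicates 2 (2.97) and 5 (2.25). Fasn was at 3.99 on that PBS array, above anti-GCGR replicate 5 (3.53). The list mean, as difference from the PBS mean, was 0.59 on PBS replicate 5 and 0.48 on anti-GCGR replicate 5. On the other antibody arrays it was 0.62 to 1.51. The NADPH-forming malic enzyme Me1 rose by 1.86 ± 0.36. Gpam, which starts triglyceride assembly, rose by 1.64 ± 0.31, and the monoacylglycerol acyltransferase Mogat1 by 1.34 ± 0.14, both with no overlap between the groups. Of 14 lipid droplet proteins 6 rose, none fell and 8 did not pass (6 rose when adjusted over the list alone), with a camera adjusted p of 0.000782 and an adjusted p = 0.423 with an estimated correlation. Its largest rises were Cidea at 2.54 ± 0.71 and Cidec at 2.21 ± 0.48 (1.62 on its other kept probe), proteins that enlarge lipid droplets. The log2 fold change of Cidec was -0.24 with the scanner software's ratio, and that of Cidea was no longer past the threshold there (adjusted p = 0.169). Between the groups the Cidec signal differed by 2.93 in Cy5 and by 0.88 in Cy3, the reference dye, on the log2 scale, and that of Fasn by 2.26 and 0.59. Cidec is also among the adipocyte markers. In the 11 fits that each left out 1 array, the Cidea call was lost in 8, and its log2 fold change was 3.15 without anti-GCGR replicate 5.

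**Figure D1:**
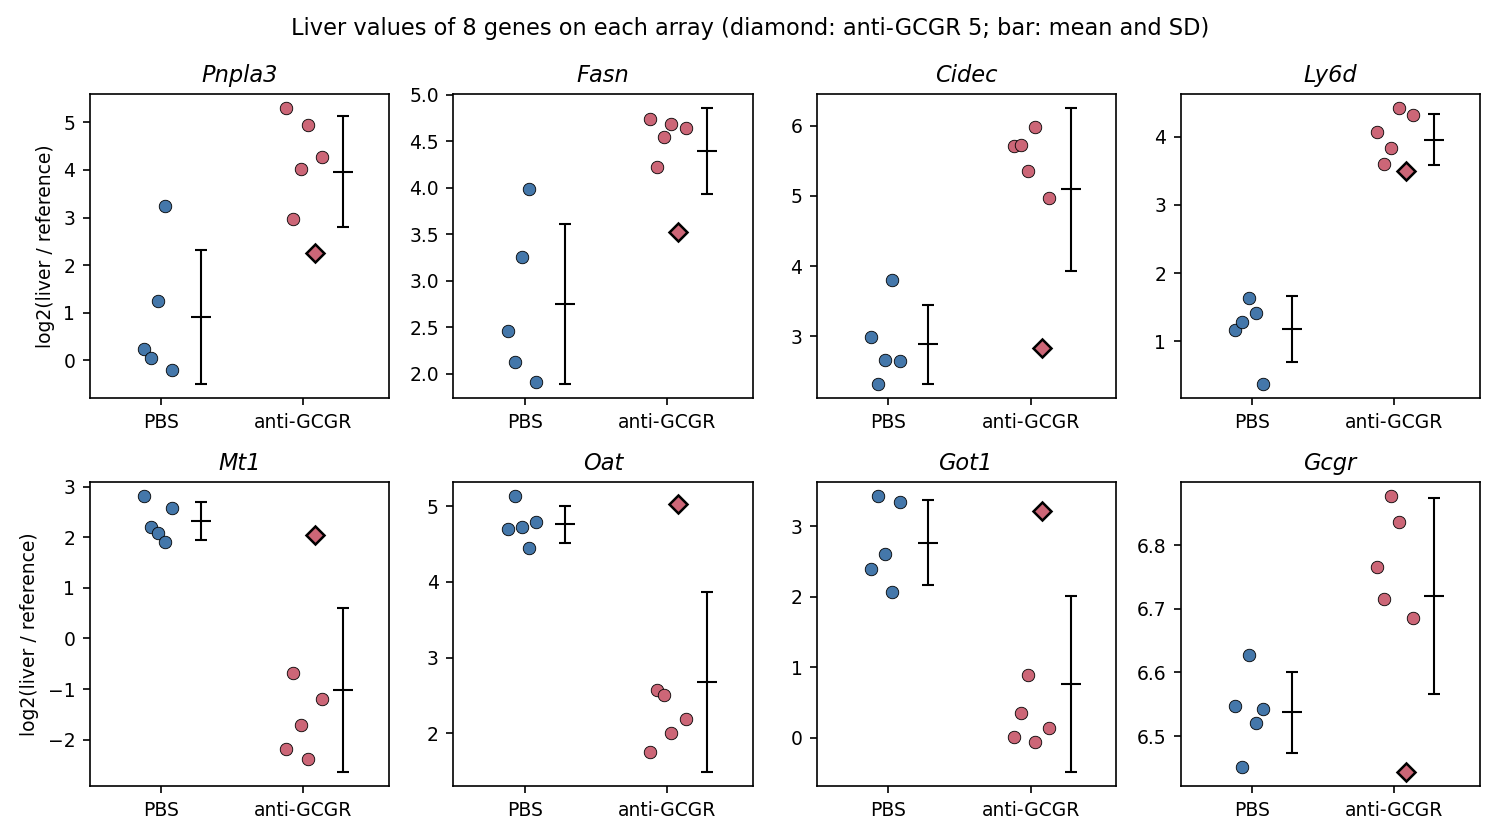
Log2 of liver over reference signal (vertical axis) for 8 genes on each array, by group (horizontal axis), with points for single arrays, a diamond for anti-GCGR replicate 5 and bars for the mean and SD. The Fasn means were 2.75 in PBS and 4.40 with antibody, and on anti-GCGR replicate 5 Mt1, Oat and Got1 lay among the PBS arrays.

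Among the lists of sugar metabolism, glycolysis and glycogen genes were called higher by camera, and gluconeogenesis enzymes were not called. In the glycolysis list 8 of 20 genes rose, none fell and 12 did not pass, and 12 rose when adjusted over the list alone (camera adjusted p = 5.94e-05, adjusted p = 0.423 with an estimated correlation). The liver pyruvate kinase Pklr rose by 1.39 ± 0.29 on the log2 scale and the glucose phosphate isomerase Gpi1 by 0.95 ± 0.25. Among 14 glycogen genes 4 rose, none fell and 10 did not pass, with 5 up when adjusted over the list alone (camera adjusted p = 0.0417, adjusted p = 0.423 with an estimated correlation). The glycogen call was lost without PBS replicate 1, 3 or 6 or anti-GCGR replicate 1 or 4 (camera adjusted p = 0.0526, 0.0525, 0.0701, 0.0753 and 0.0514). The risers included the branching enzyme Gbe1 (0.83 ± 0.19) and the liver phosphorylase Pygl (0.52 ± 0.11), which build and break down glycogen. Gluconeogenesis enzymes were not called as a list (camera adjusted p = 0.832): 2 of 11 rose, none fell and 9 did not pass, and 2 rose and 2 fell when adjusted over the list alone. The risers were Pcx, pyruvate carboxylase (0.39 ± 0.11), and Gpd1, glycerol phosphate dehydrogenase (0.22 ± 0.06). For Pck1, the PEP carboxykinase of gluconeogenesis, the log2 fold change was -0.29 ± 0.09 (limma adjusted p = 0.0559), and for G6pc, the glucose-releasing phosphatase, 0.28 ± 0.11 (adjusted p = 0.103), which was 0.36 without anti-GCGR replicate 5 (adjusted p = 0.00884). Among the 11 fits with 1 array left out, the call was lost in 10 for Gpd1, 9 for Pcx and 7 for Gpi1, and Pck1 passed in 2.

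The list of genes that break down amino acids was lower by camera, and most of its members did not pass. Of 56 measured genes of amino acid catabolism 18 fell, 2 rose and 36 did not pass, and 24 fell and 3 rose when adjusted over the list alone (camera adjusted p = 3.94e-07, adjusted p = 0.432 with an estimated correlation, fry adjusted p = 0.0610). Got1, the cytosolic aspartate aminotransferase, fell by 2.01 on the log2 scale (SE 0.51, limma adjusted p = 0.0226), and Acmsd, of tryptophan breakdown, fell 2.83-fold. The liver glutaminase Gls2 went from 5.33 ± 0.13 (SD, n = 5) to 4.61 ± 0.41 (SD, n = 6), a log2 fold change of -0.72 ± 0.16 (limma adjusted p = 0.0152). The 2 members that rose were Csad, which makes taurine from cysteine products (1.12 ± 0.31), and the aspartate oxidase Ddo (0.81 ± 0.17, and 0.27 on its other kept probe). Tat, the tyrosine aminotransferase, had a log2 fold change of -0.30 ± 0.10 (adjusted p = 0.0631). In the urea cycle list 2 of 8 genes fell, none rose and 6 did not pass, and 4 fell when adjusted over the list alone (camera adjusted p = 0.0300, adjusted p = 0.560 with an estimated correlation). The fallers were Ass1 (-0.81 ± 0.24), which makes argininosuccinate, and the ornithine carrier Slc25a15 (-0.76 ± 0.16). Cps1, the entry enzyme of the cycle, was at -0.35 ± 0.13 (adjusted p = 0.0841) and at 0.11 with the scanner software's ratio. Amino acid transporters went the same way, with 9 of 22 down, 2 up and 11 not passing, and 10 down and 2 up when adjusted over the list alone (camera adjusted p = 0.0420, adjusted p = 0.423 with an estimated correlation). The urea cycle call was lost without PBS replicate 4 or 6 or anti-GCGR replicate 1 (camera adjusted p = 0.0638, 0.0589 and 0.0511), and the transporter call without PBS replicate 1 or 6 or anti-GCGR replicate 1 (0.0526, 0.0933 and 0.0561). Got1 did not pass without PBS replicate 3 or 6 or anti-GCGR replicate 4 (log2 fold change -1.84, -1.86 and -1.84). Slc3a1 fell by 1.39 (SE 0.26), Slc16a10 by 0.96 (SE 0.22, and by 0.14 on its other kept probe) and Slc38a4 by 0.50 (SE 0.15), and Slc6a9 and Slc7a8 rose by 0.52 and 0.42. Over the 11 fits with 1 array left out, the call was lost in 10 for Ass1, 10 for Slc38a4, 8 for Csad, 5 for Slc6a9, 2 for Acmsd and 1 for Slc7a8, and in none for Slc25a15, and Tat passed in 2 and Cps1 in 1.

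Among genes of the cAMP and fasting response 3 of 19 fell, none rose and 16 did not pass, also when adjusted over the list alone (camera adjusted p = 0.0306, adjusted p = 0.423 with an estimated correlation). The list call was lost without PBS replicate 3 or 6 (camera adjusted p = 0.0517 and 0.0701). Ppargc1a, the coactivator of the fasting liver, fell by 0.80 on the log2 scale (SE 0.11, limma adjusted p = 0.00419) with no overlap between the groups. Kiss1, the kisspeptin precursor that glucagon induces in liver, fell by 0.66 (SE 0.13, and by 0.33 on its other kept probe). The Gcgr transcript itself was at 6.54 ± 0.06 (SD, n = 5) in PBS and 6.72 ± 0.15 (SD, n = 6) with antibody, a log2 fold change of 0.18 ± 0.07 (limma adjusted p = 0.107, two-sided exact permutation p = 0.0433). Without anti-GCGR replicate 5 the Gcgr log2 fold change was 0.24 (adjusted p = 0.00771). Hormone receptors and secreted hormones went both ways, with 4 of 29 up, 3 down and 22 not passing (6 up and 5 down when adjusted over the list alone, camera adjusted p = 0.637). Inhba, the activin A subunit, rose by 0.77 ± 0.19 and the adiponectin receptor Adipor2 by 0.65 ± 0.11, and Hamp2, a hepcidin gene, fell by 0.49 (SE 0.13). For Fgf21, the fasting hormone, the log2 fold change was 1.73 ± 0.59 (adjusted p = 0.0674), 2.18 without anti-GCGR replicate 5 (adjusted p = 0.00392) and 2.14 without PBS replicate 5 (adjusted p = 0.0301). The call was lost in 7 of the 11 fits with 1 array left out for Hamp2 and in 2 for Inhba.

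In the remaining metabolic lists few members passed. Of 30 genes of fatty acid oxidation and ketogenesis 7 rose, none fell and 23 did not pass, with the same 7 up when adjusted over the list alone (camera adjusted p = 0.0256, adjusted p = 0.690 with an estimated correlation). That call was lost without PBS replicate 6 or anti-GCGR replicate 2 (camera adjusted p = 0.0584 and 0.0651). Cpt1b, a carnitine acyltransferase, rose by 0.72 ± 0.20 and the pantetheinase Vnn1 by 0.66 ± 0.19, and the liver form Cpt1a was at 0.18 ± 0.14 (adjusted p = 0.409). Oxidative phosphorylation genes were called lower as a list (mean log2 fold change -0.09, camera adjusted p = 0.000782, adjusted p = 0.751 with an estimated correlation). Only Atp5c1 (-0.25 ± 0.07) of its 36 members passed over all genes, and none did when adjusted over the list alone. No call was made for 25 cholesterol synthesis genes (camera adjusted p = 0.108; 2 fell, among them Ebp by 0.49, none rose, 1 fell when adjusted over the list alone). The mean of the cholesterol list was 0.26 and depended on single arrays. It was 0.13 without anti-GCGR replicate 1 (camera adjusted p = 0.382), and the list was called without anti-GCGR replicate 2, 5 or 6 (0.0364, 0.0256 and 0.0319) and with slide as a block (0.0341). Bile acid genes were not called either (camera adjusted p = 0.429; 2 of 24 rose and 1 fell, also when adjusted over the list alone). Nr1h4, the bile acid receptor, and the phospholipid pump Abcb4 rose by 0.23 and 0.20. The bile acid importer Slc10a1 fell by 0.31 on its brightest probe and was at 0.005 over all its probes. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.04 ± 0.41 (adjusted p = 0.110), at -1.25 without anti-GCGR replicate 5 (adjusted p = 0.0338) and at -1.32 without anti-GCGR replicate 3 (adjusted p = 0.0398). Of the 11 fits with 1 array left out, the call was lost in 10 for Abcb4, Slc10a1 and Atp5c1, in 8 for Nr1h4, in 7 for Cpt1b and Vnn1 and in 5 for Ebp.

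Lists of hepatocyte function and stress were not called by camera with all arrays, and several were called with 1 array left out. Drug-metabolizing enzymes (1 of 40 up, 2 down, also when adjusted over the list alone, camera adjusted p = 0.108) included falls of Cyp3a44 by 1.23 and of the sulfotransferase Sult2a1 by 1.02, and a rise of the epoxide hydrolase Ephx1 by 0.32. Growth hormone and sex-dependent genes (3 of 27 up, 3 down, 4 up and 3 down when adjusted over the list alone, camera adjusted p = 0.486) included rises of Cish by 1.18 and Mup20 by 0.94 (0.19 on its other kept probe) and a fall of Cyp17a1 by 0.63. Acute phase proteins (2 of 24 up, 3 down, also when adjusted over the list alone, camera adjusted p = 0.246) held the metal-binding metallothioneins, where Mt1 fell by 3.34 (SE 0.63, limma adjusted p = 0.0077) and Mt2 by 4.03 (SE 0.75, limma adjusted p = 0.00743). Cebpd and Cp of that list rose by 0.66 and 0.52. The amino acid and unfolded protein stress list had 4 of 28 up and 1 down (6 up and 3 down when adjusted over the list alone, camera adjusted p = 0.578), with Atf3 and Psph up by 0.51 and 0.41 and Vldlr down (-0.44). Pericentral genes (5 of 25 down, none up, 6 down and 1 up when adjusted over the list alone, camera adjusted p = 0.148) were led by Oat, ornithine aminotransferase, which fell by 2.08 (SE 0.46), and Lhpp, which fell by 1.33 (0.62 on its other kept probe). Periportal genes (2 of 24 up, 2 down, 2 up and 5 down when adjusted over the list alone, camera adjusted p = 0.0502) included Apoa4, at 1.48 ± 0.44 here and at -0.29 with the scanner software's ratio. Hsd17b13, of that list and of the lipid droplet list, rose by 0.35 (0.08 on its other kept probe). Of 18 clock genes 1 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.0642, though called lower by fry, adjusted p = 0.0428), with falls of Nr1d2 (-0.31 ± 0.07) and Cry2 (-0.30 ± 0.05). None of 32 ribosomal protein genes passed over all genes or when adjusted over the list alone (camera adjusted p = 0.198; Rpl3, with the smallest p, at 0.30, adjusted p = 0.0582). Without PBS replicate 5 the periportal, pericentral, drug-metabolizing, clock and acute phase lists were called lower (camera adjusted p = 0.0227, 0.0335, 0.0218, 0.0371 and 0.0472). Periportal genes were also called without PBS replicate 3 or anti-GCGR replicate 2, 3 or 4 (0.0255, 0.0386, 0.0205 and 0.0411), clock genes without anti-GCGR replicate 2 or 4 (0.0395 and 0.0308) and acute phase proteins without PBS replicate 3 (0.0497). Pericentral genes and drug-metabolizing enzymes were called without anti-GCGR replicate 3 (0.0405 for each), and ribosomal proteins were called higher without anti-GCGR replicate 4 or 6 (0.0411 and 0.0123). Single genes of these lists depended on the arrays too. With 1 array left out the call was lost in 9 of 11 fits for Cp, Cyp17a1, Apoa4 and Hsd17b13, 8 for Atf3, Vldlr and Mup20, 6 for Ephx1, 5 for Cebpd and Cish and 2 for Sult2a1, and Rpl3 passed in 2. Without anti-GCGR replicate 5 the log2 fold changes of Mt1 and Mt2 were -3.95 and -4.74.

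**Figure D2:**
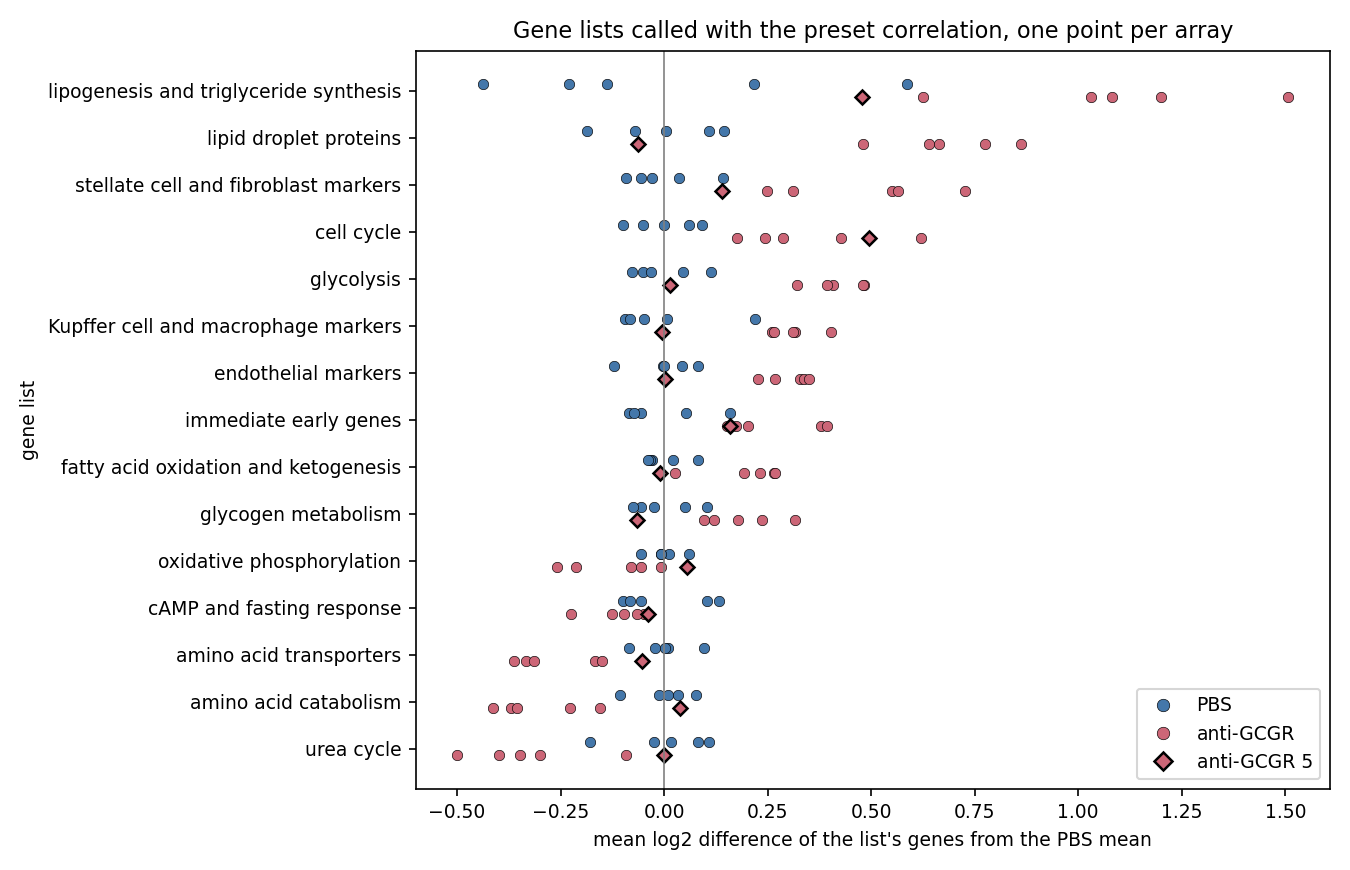
Mean log2 difference from the PBS mean over the measured genes of each list (horizontal axis) for the 15 lists called with the preset correlation (vertical axis), with one point per array and a diamond for anti-GCGR replicate 5. The lipogenesis list has a mean log2 fold change of 0.99 and the amino acid catabolism list of -0.25, and no list passed with an estimated correlation.

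Cell cycle genes were higher with antibody. Of 28 measured genes 16 rose, none fell and 12 did not pass, and 25 rose when adjusted over the list alone (camera adjusted p = 1.11e-09, adjusted p = 0.423 with an estimated correlation). The replication helicase subunit Mcm6 rose by 1.01 ± 0.22 and cyclin D1, Ccnd1, by 0.97 ± 0.16, both with no overlap between the groups. Their PBS means were -4.43 and -2.68, below the reference signal, as were those of Jun and Egr1 below (-3.25 and -5.28). In the immediate early list 6 of 21 genes rose, none fell and 15 did not pass, and 8 rose when adjusted over the list alone (camera adjusted p = 0.0256, adjusted p = 0.560 with an estimated correlation), with Jun at 0.89 ± 0.18 and Egr1 at 0.53 ± 0.15. The immediate early call was lost without PBS replicate 4 (camera adjusted p = 0.0758). That of Egr1 was lost in 6 of the 11 fits with 1 array left out.

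Markers of connective tissue, vessel and macrophage cells rose beside them. Of 17 stellate cell and fibroblast markers 9 rose, none fell and 8 did not pass, and 11 rose when adjusted over the list alone (camera adjusted p = 9.22e-06, adjusted p = 0.423 with an estimated correlation). The collagens Col1a1 and Col3a1 rose by 1.57 ± 0.29 and 1.09 ± 0.19. Their PBS means were -6.39 and -3.83, far below the reference signal, though well above background in Cy5 on every array. The same held for the macrophage genes Trem2 and Gpnmb below, with PBS means of -3.22 and -3.90. Of 15 endothelial markers 5 rose, none fell and 10 did not pass (9 rose when adjusted over the list alone, camera adjusted p = 0.000228, adjusted p = 0.423 with an estimated correlation). Vwf was at 0.44 ± 0.11, and Cdh5 was at 0.38 ± 0.11 here and at -0.07 with the scanner software's ratio. Of 19 Kupffer cell and macrophage markers 6 rose, none fell and 13 did not pass (8 rose when adjusted over the list alone, camera adjusted p = 0.000558, adjusted p = 0.423 with an estimated correlation), with the lipid-associated macrophage genes Trem2 at 0.90 ± 0.17 and Gpnmb at 0.55 ± 0.15. Hepatocyte markers were not called (camera adjusted p = 0.462): Serpina1c of 15 fell by 0.26, none rose, none passed when adjusted over the list alone, and Serpina1c was at 0.03 with Cy5 alone. The other cell type lists were not called. Pkhd1 alone of 9 cholangiocyte markers rose (0.67 ± 0.13, camera adjusted p = 0.578), Cd4 alone of 12 lymphocyte markers (0.57 ± 0.15, and -0.01 on its other kept probe, camera adjusted p = 0.846), and each also when adjusted over its list alone. Of 5 erythroid markers Slc4a1, Hba-a1 and Hbb-b2 rose and Car1 fell, also when adjusted over the list alone (0.42, 0.21, 0.19 and -0.74, camera adjusted p = 0.229). Adipocyte markers had Cidec up and Lipe down (-0.30 ± 0.07) among 9, with 3 up and 2 down when adjusted over the list alone (camera adjusted p = 0.596). None passed, over all genes or when adjusted over the list alone, of 7 neutrophil, 9 pancreatic acinar and 6 skeletal muscle markers (camera adjusted p = 0.486, 0.846 and 0.702). The smallest p there belonged to Mpo (0.54), Cela1 (0.23) and Acta1 (0.33). Without PBS replicate 5 the neutrophil list was called (mean 0.40 against 0.19, camera adjusted p = 0.0227) and Mpo passed (0.86, adjusted p = 0.0231). Mean, median and test differed in sign for the lymphocyte and acinar lists. Leaving out 1 array at a time, the call was lost in 9 of 11 fits for Cdh5, 8 for Gpnmb, 7 for Serpina1c, 4 for Vwf, 3 for Cd4 and 1 for Lipe, and Cela1 passed in 1.

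Outside the lists, the largest rises without overlap between the groups were those of Ly6d, Rad51b, Ifi27l2b, Cabp2 and Tubb2a. Ly6d, a surface protein best known from B cell precursors, rose from 1.18 ± 0.48 (SD, n = 5) to 3.96 ± 0.38 (SD, n = 6), by 2.78 ± 0.22 (SE, limma adjusted p = 0.000198). Rad51b, of DNA repair, rose by 2.28 ± 0.33, the interferon-induced Ifi27l2b by 2.27 ± 0.29 (0.29 on its other kept probe), the calcium-binding Cabp2 by 1.77 ± 0.38 and the tubulin Tubb2a by 1.55 ± 0.23. The largest falls without overlap were those of Sult2a4 (-1.96 ± 0.56), Mmd2 (-1.91 ± 0.30), the transporter Slc22a26 (-1.81 ± 0.31), Lrtm2 (-1.10 ± 0.20), Nkd2 (-1.06 ± 0.20) and Tuba8 (-1.06 ± 0.18), beside Slc3a1 and Sult2a1. Sult2a4 was at 0.13 with the scanner software's ratio. Values of close gene copies (Sult2a1 and Sult2a4, Mt1 and Mt2, Mup20, Cyp3a44, Scd1, Tubb2a and the globins) are uncertain, since a probe can bind a sister transcript. The Sult2a4 call was lost in 6 of the 11 fits with 1 array left out, and the Sult2a1 call in 2.

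One antibody array stood apart. On the first principal component, with 50.6% of the variance, anti-GCGR replicate 5 lay at -12.5, among the PBS arrays (-19.2 to -9.92), and the other antibody arrays lay between 13.3 and 23.8. Without it 2294 genes rose and 1576 fell (3870 in all, 158 at least 2-fold), 16 lists were called and none passed with an estimated correlation. On that array the mean log2 difference from the PBS mean was 0.49 over cell cycle genes, above every PBS array (at most 0.09). Over lipogenesis genes it was 0.48, within the range of the PBS arrays (-0.44 to 0.59). It was 0.14 over stellate markers, 0.04 over amino acid catabolism genes, 0.002 over endothelial markers and -0.01 over Kupffer markers. The gene count also moved by more than 1.5 times without PBS replicate 1 (1237), PBS replicate 3 (1419), PBS replicate 4 (1534) or anti-GCGR replicate 4 (1399).

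**Figure D3:**
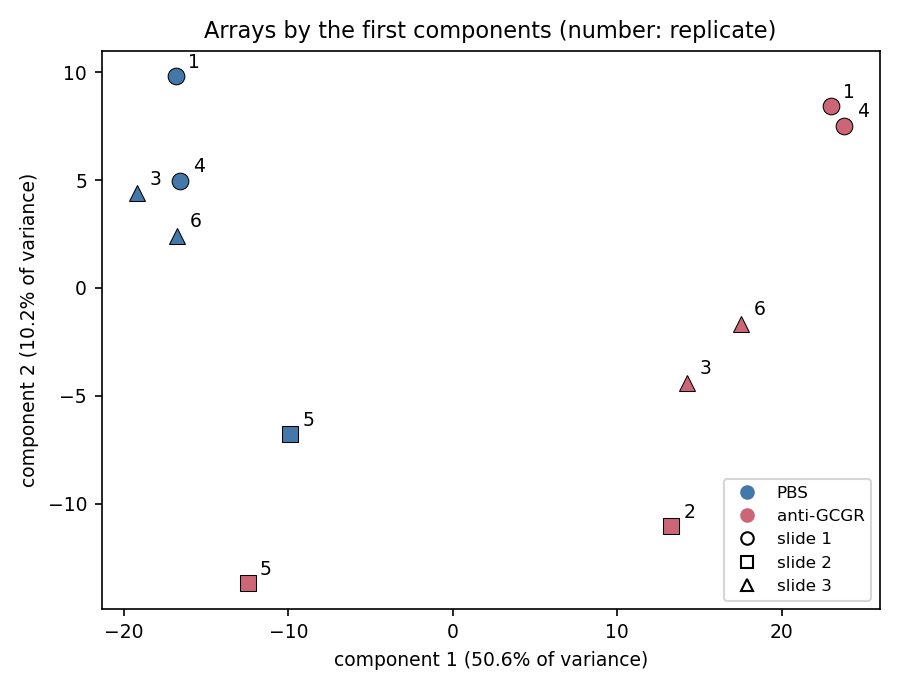
Arrays along the first component (horizontal axis, 50.6% of variance) and the second (vertical axis), coloured by group, shaped by slide and numbered by replicate. Anti-GCGR replicate 5 lies at -12.5 on the first component, between PBS replicate 5 at -9.92 and PBS replicate 4 at -16.6.

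The arrays lay on 3 slides that each held both groups. With slide as a block 2788 genes were called. Within slide 1 there were 1221, and within slide 3 there were 502. Within slide 2 there were 0, with 957 at an unadjusted p under 0.05 (limma). That slide held a single PBS array, PBS 5, beside anti-GCGR 2 and 5, so the PBS group had no replicate there and was assumed to vary like the antibody group. Mean log2 fold changes within slides 1, 2 and 3, after the blocked value, were as follows. They were 1.005, 1.31, -0.04 and 1.39 for lipogenesis, -0.26, -0.42, 0.01 and -0.28 for amino acid catabolism, 0.37, 0.45, 0.05 and 0.49 for glycolysis, and 0.58, 0.71, 0.21 and 0.69 for lipid droplets. For the cell cycle they were 0.38, 0.38, 0.37 and 0.38, for stellate markers 0.45, 0.47, 0.28 and 0.55, for endothelial markers 0.27, 0.24, 0.29 and 0.29, and for Kupffer markers 0.27, 0.33, 0.28 and 0.20. Amino acid transporters had -0.24, -0.34, -0.03 and -0.28, the urea cycle -0.28, -0.49, 0.03 and -0.27, and cAMP and fasting genes -0.10, 0.02, 0.004 and -0.29. Glycogen genes had 0.16, 0.26, -0.09 and 0.21, fatty acid oxidation 0.17, 0.20, 0.11 and 0.17, immediate early genes 0.25, 0.34, 0.10 and 0.26, and oxidative phosphorylation -0.11, -0.17, 0.01 and -0.13. The Gcgr log2 fold change was 0.20 with the block and 0.21, 0.06 and 0.28 within the slides. On every slide PBS arrays lay at positions 1 and 2 and antibody arrays at positions 3 and 4, so array position and treatment cannot be told apart.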

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

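All tests in this part were chosen after the results were seen, except those on other splits of the arrays and the test without Col1a1, Col3a1, Trem2 and Gpnmb. An array was singled out when its gap to the nearest array of its group, as a share of the group's range, passed Dixon's critical value. Of 294 groups of values tested, 26 had such an array where chance gives about 14.7, and 18 of them were at anti-GCGR replicate 5 and 5 at PBS replicate 5.

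Anti-GCGR replicate 5 lay with or toward the PBS arrays for many genes. The gap was 0.837 of the range for Apoa4, 0.793 for Kyat3, 0.789 for Psph, 0.772 for Gbe1, 0.765 for Mmd2, 0.751 for Oat, 0.735 for Cp and 0.733 for Lhpp. It was 0.713 for Cyp3a44, 0.71 for Got1, 0.681 for Cidec, 0.681 for Hsd17b13, 0.654 for Ifi27l2b and 0.628 for Ddo. Among gene lists it was 0.654 for glycolysis, 0.652 for Kupffer cell and macrophage markers and 0.646 for endothelial markers. For the muscle actin Acta1 (0.647) this array lay above all others.

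Over genes changed at least 2-fold without it, anti-GCGR replicate 5 showed a median share of 0.0508 of the change, against 0.805 to 1.13 on the other antibody arrays. A poor array does not account for this by the measures taken, since 0 of 3 lay outside the range of the other arrays. They were the share of spots well above background in Cy5, outlier spots and the correlation of the Cy3 signal with other arrays. None of them rates the liver RNA itself, so a poor sample was not tested. A slide effect shared by both antibody arrays of the slide does not account for most of the low share. Anti-GCGR replicate 2 of the same slide showed a median share of 0.8053. That rests on 1 array, whose share was the lowest of the other antibody arrays. Arrays did differ by slide on the second component, with slide 1 at 4.97 to 9.82 and slide 2 at -13.7 to -6.76. More genes lay beyond the remaining PBS arrays on this array than on the PBS array left out in 4 of 5 comparisons. The counts were 11 against 2, 15 against 2, 12 against 4 and 14 against 12. Neither these counts nor the cell cycle mean (0.49, PBS at most 0.09) can decide against a PBS liver. The counts would have had to be higher in all 5 comparisons. The array also lay at a position that held no PBS array, and the cell cycle list was singled out after its values were seen. Ly6d (3.50, PBS at most 1.64), Mogat1 (3.66, PBS at most 2.83) and Sult2a4 (6.41, PBS at least 7.90) cannot decide. They were chosen among genes whose groups, with this array included, do not overlap. Against PBS replicate 5 the count was 19 to 41, an excess of -22, so that PBS arrays alone can differ by more. A PBS liver under the wrong label is thus not excluded and cannot be told apart from a mouse that responded to little antibody, which may also be the cause and was not tested.

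The Cy3 signal of the reference RNA, the same on every array, differed between the groups for 247 genes (68 higher and 179 lower with antibody, limma), with 1911 at an unadjusted p under 0.05. Of these 247 genes 117 were also called in the ratio, 23 of them in the opposite direction. A gradient over array positions does not account for it, as the correlation of the difference per position step within groups with the difference between groups was -0.2287. Liver signal reaching the Cy3 channel is consistent with the tests. Among genes changed at least 2-fold, Cy3 moved with Cy5 in 40 of 46 genes (86.96%) with Cy5 at least 4 times Cy3, and in 10 of 26 (38.5%) with Cy5 below Cy3 (Fisher's exact test, one-sided p = 3.03e-05). That p counts genes of the same arrays as independent and does not measure the spread between arrays. The genes were also chosen by the ratio, which holds both dyes, so the choice is not independent of how Cy3 moved. A step between the array positions of the groups stays open for the rest.

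Markers of stellate, endothelial and Kupffer cells rose together, by 0.31 on the log2 scale over the 3 lists (exact permutation p = 0.00866, two-sided). A lower share of hepatocytes would raise markers of all other liver cells alike, provided that dim and bright markers respond alike on these arrays. The 3 lists rose by more than cholangiocyte and lymphocyte markers (by 0.25, exact permutation p = 0.0130, two-sided). They also rose by more than these with neutrophil and erythroid markers (by 0.23, exact p = 0.0433). This argues against a lower share of hepatocytes as the whole cause only under that condition, which was not tested. The margin was narrow and the lists had already been seen. Against the mean of all 7 other lists the excess was 0.20 (exact p = 0.04978). That comparison cannot decide, since the 7 hold acinar, muscle and adipocyte markers, of cells that a piece of liver need not hold. Adipocyte markers, Cidec among them, had a mean of 0.37, above that of the 3 lists. Since the 7 lists rose by 0.11 themselves (exact p = 0.0195), at least a part stays open. The collagen genes Col1a1 and Col3a1 and the phagocyte genes Trem2 and Gpnmb alone do not account for the rise. Without them the shift was 0.25 (exact permutation p = 0.008658, two-sided). The lists still held other collagen and phagocyte genes, so the test cannot decide on such genes as a class. More of these cells, or more transcript per cell, stay open as hypotheses.

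The other arrays singled out were PBS replicate 5 for Meg3 (0.89), Fgf21 (0.884), Gpi1 (0.868), Mpo (0.867) and Slc2a4 (0.768), PBS replicate 4 for Pkhd1 (0.754) and PBS replicate 3 for Nr1d2 (0.724). Anti-GCGR replicate 2 stood apart for Cebpd (0.656). Among 7646 transcripts whose accession matched no gene name, 601 differed between the groups (299 higher and 302 lower with antibody).

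The real split of the 11 arrays into 5 and 6 was set beside others drawn at random from the 462 possible, 100 in all. Among these only the real one (1 of 100) gave 2337 changed genes, and only the real one (1 of 100) gave 98 genes at 2-fold. The split that exchanges PBS replicate 5 for anti-GCGR replicate 5 was not drawn, so a count as high in a split not drawn is not excluded. The next highest counts were 1618 and 75, both in a split that put anti-GCGR replicate 5 with PBS replicates 1, 3, 4 and 5. As many as 15 shifted gene lists came up in 17 of 100 splits, with up to 19 in one, so that the number of lists called with the preset correlation is no larger than other splits of these arrays give.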

How the results depend on the processing

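Tests without the replicate block on the shared numbers, with unnamed transcripts, and with an estimated correlation without anti-GCGR replicate 5 were chosen after seeing the data. Quantile scaling of brightness alone moved no ratio and was left out. Of 100 named genes past the threshold, 59 stayed past it in every alternative of processing (fits by slide or replicate number aside) and 56 with each array left out. Of 15 lists, 7 and 9 did. The authors' processed values moved no direction or call of a named gene or list, and called 2316 genes, of which 2312 are among the 2337. Causes were not tested unless named.

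The number of changed genes was 3798 with array weights, 465 at an adjusted p under 0.01, 1221, 0 and 502 within slides 1, 2 and 3, and 1034 with the replicate block on the 5 shared numbers, where 1809 were called without the block. No array correlated best with its own number in the other group, which gives no sign of pairing by number. These 5 pairs cannot exclude it, and each shared number lay on the same slide in both groups. Genes at 2-fold numbered 175 with the scanner software's ratio, 195 and 0 within slides 1 and 2, and 52 with the replicate block. Shifted gene lists numbered 9 with the scanner software's ratio and 0 with an estimated correlation, with or without anti-GCGR replicate 5. The Gcgr log2 fold change was 0.2224 with array weights (adjusted p = 0.0195). With each array left out in turn, changed genes ranged from 1237 to 3870, genes at 2-fold from 66 to 158, shifted lists from 10 to 21 and the Gcgr level from 0.1514 to 0.2382.

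With the scanner software's ratio these log2 fold changes reversed: Cps1 0.1108, Sult2a4 0.1309, Cidec -0.2421, Apoa4 -0.2902 and Cdh5 -0.06881, and the list means of gluconeogenesis enzymes -0.02742, erythroid markers -0.05803, adipocyte markers -0.0397 and pancreatic acinar markers -0.2047.

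With median centring in place of loess the list means reversed for gluconeogenesis enzymes (-0.03636), bile acid synthesis and transport (-0.04048), the amino acid and unfolded protein stress response (-0.009811), T, NK and B lymphocyte markers (-0.03902), erythroid markers (-0.06208), pancreatic acinar markers (-0.0274) and skeletal muscle markers (-0.01748).

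With Cy5 alone Serpina1c was at 0.03324, and the means of bile acid synthesis and transport at -0.009606, hepatic hormone receptors and secreted hormones at -0.009549, hepatocyte markers at 0.1215 and pancreatic acinar markers at -0.002455. Hepatocyte markers were at 0.01823 with scale normalization. Growth hormone and sex-dependent liver genes were at 0.002941 with no background subtraction and 0.04927 with a filter in both channels. With the mean of all probes of a gene Slc10a1 was at 0.005436 and pancreatic acinar markers at -0.004194, and the latter were at -0.01248 with the replicate block and on the same arrays without it. Erythroid markers were at -0.008768 with array weights.

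Within slide 1 list means reversed for the cAMP and fasting response (0.01764), bile acid synthesis and transport (-0.04237), erythroid markers (-0.1461) and pancreatic acinar markers (-0.03434). Within slide 3 Cpt1a was at -0.01548, ribosomal proteins at -0.02422 and T, NK and B lymphocyte markers at -0.03255.

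Within slide 2, which holds anti-GCGR replicates 2 and 5 and PBS replicate 5 as its only PBS array, these genes reversed: Pck1 0.07232, Tat 0.08691, Cps1 0.08301, Fgf21 -0.9152, Pygl -0.01386, Fasn -0.1128, Slc6a9 -0.02413, Pcx -0.02086, Pklr -0.08352, Gpi1 -0.1095, Pnpla3 -0.6344, Inhba -0.01569, Apoa4 -0.1022, Mpo -0.6644, Slc2a4 -0.2258, Rpia -0.05829, Acly -0.2401, Elovl6 -0.1423, Scd1 -0.2309 and Acaca -0.1371. List means reversed there for amino acid catabolism (0.01136), urea cycle (0.02942), cAMP and fasting response (0.004043), glycogen metabolism (-0.08814), lipogenesis and triglyceride synthesis (-0.03574), cholesterol synthesis (-0.08199), drug-metabolizing enzymes (0.1316), amino acid and unfolded protein stress response (-0.03172), acute phase proteins (0.2335), growth hormone and sex-dependent liver genes (0.2876), pericentral hepatocyte genes (0.08568), periportal hepatocyte genes (0.07589), circadian clock (0.03848), oxidative phosphorylation (0.01277), hepatocyte markers (0.0788), T, NK and B lymphocyte markers (-0.03523) and neutrophil markers (-0.5498).

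With each array left out the list means ranged from -0.06131 to 0.02193 for growth hormone and sex-dependent liver genes, from -0.05126 to 0.01175 for hepatocyte markers, from -0.02077 to 0.05164 for erythroid markers and from -0.01248 to 0.01377 for pancreatic acinar markers. The Cy5 median of 85 to 110 over a background of 26 to 27 limits what can be seen of dim transcripts.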

Other observations

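The genes in this part were chosen after their values were seen, and no tests beyond the fit were run on them. The pentose phosphate pathway supplies NADPH for fat synthesis and was not tested as a list. Of 9 measured enzymes of the pathway 5 rose, none fell and 4 did not pass. Pgd rose by 1.06 ± 0.20 on the log2 scale (SE, limma adjusted p = 0.00834), Rpia by 1.01 ± 0.21, Tkt by 0.92 ± 0.18 and Taldo1 by 0.41 ± 0.07, the last with no overlap between the groups. Enzymes of fatty acid synthesis that rose beside Fasn included Elovl6 at 1.85 ± 0.38, Acly at 1.82 ± 0.44 (0.80 on its other kept probe), Scd1 at 1.65 ± 0.49 and Acaca at 1.30 ± 0.29 (0.62 and 0.71 on its other kept probes). With 1 array left out in turn, the Scd1 call was lost in 8 of 11 fits (1.14 to 2.02) and the Acly call in 1. Slc2a4, the insulin-dependent glucose transporter of muscle and fat, rose by 1.82 ± 0.42.

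The imprinted noncoding transcripts Meg3 and Mirg, of one locus, fell by 2.53 (SE 0.45, limma adjusted p = 0.00639) and 1.65 (SE 0.32, limma adjusted p = 0.00857) on the log2 scale. The other kept probes of Meg3 were at -2.15 and -1.28. Hao2, a peroxisomal hydroxy acid oxidase, fell by 2.03 (SE 0.50), Cth, of cysteine synthesis, by 1.27 (SE 0.33), and Kyat3, of tryptophan breakdown, by 1.07 (SE 0.19, and by 0.62 on its other kept probe). The zinc importer Slc39a4 fell by 1.06 (SE 0.29) beside the metal-binding Mt1 and Mt2. Cx3cr1, a chemokine receptor of monocytes and macrophages, rose by 1.14 ± 0.23 (0.43 on its other kept probe). Leaving out single arrays, the call was lost in 7 of 11 fits for Slc39a4, 6 for Cth and 1 for Hao2.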
